A study of Arabidopsis thaliana with 12 samples.

How the data were processed

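The series holds 12 array hybridisations of Arabidopsis thaliana total RNA, 6 from the wild type (WT) and 6 from the ppi1 mutant, both given as ecotype Columbia 0 in the labels. The groups and the replicate numbers 1 to 6 were taken from the sample titles. The labels do not say whether the replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. Tissue, plant age, array type and scanner are not given in the sources used here.

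The deposited table gives 1 hybridisation intensity per feature and array, on a linear scale and with no negative value. How the authors subtracted background and scaled these intensities is not given in the sources used here. Each array listed between 149 and 200 of the 3439 features at exactly 0. Values at a ceiling of 100 occurred on 4 arrays, for 1 to 3 features each. The array medians lay between 0.475 and 0.645, so the arrays were not on a common median. By a rule fixed before the data were examined (medians and 75th percentiles within 10% of each other), the table was therefore not taken as already normalised.

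The 74 features at 0 on every array were treated as blanks and left out, which left 3365; that a feature at 0 throughout counts as a blank was decided after the table was seen. The intensities were quantile-normalised between arrays. Values below a floor of 0.118, the 5th percentile of the positive normalised values, were set to that floor, and log2 was taken. ppi1 was compared with WT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 12 arrays, with no covariate. A feature passed the test at a two-sided Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values below are from this fit unless another is named. Levels are given as quantile-normalised relative intensity, mean ± SD over 6 arrays per group. Levels of different features were set against each other only to group, rank or match features by brightness, not to compare amounts of transcript. The number of arrays limits the precision.

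Features were named through the platform annotation of 2016, with symbols updated by gene identifier against the gene table of assembly TAIR10.1. Of the 3439 features, 692 had 1 gene, 870 had several and 1877 had none in that annotation. Of the 692 identifiers, 2 were not in the gene table and kept their old name. No feature was named from several genes. Whether the annotation is right for each feature was not tested here, and a feature can also pick up close relatives of its gene. No coordinates are given because the table names no genome build.

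Before the data were examined, 19 gene lists were fixed by locus (343 loci) and 10 by words. The plan was to search gene descriptions. The words were instead searched in the gene symbols and synonyms, so the members of the word lists were not those planned. Only 16 of the 343 loci were measured by a feature with 1 gene, so only 2 lists reached the minimum of 3 measured features. One more list, joining the 5 photosynthesis lists, was added after the names and some values had been seen. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. The genes named in the text followed a rule fixed in advance. It took the measured import genes, the 10 largest increases and the 10 largest decreases past the threshold with a gene name, and from each list the 2 largest changes in each direction past the threshold, or its smallest adjusted p where none passed. Other measured members of the lists, tested or not, are given as values. Genes named outside both the rule and the lists are marked as such.

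Same-numbered WT and ppi1 arrays deviated together from their group means. Their correlations were 0.379 to 0.590, and each array correlated best with its own number in the other group, so the numbers were taken to pair the arrays. This pairing comes from the data, since the labels say nothing of a shared day or batch. A fit with the replicate number as a block is given where it changed a call or a count by more than 1.5 times. The other alternatives fixed in advance were the deposited scale, median scaling, cyclic loess, an offset in place of the floor, a filter on dim features, an intensity trend with robust estimation, array weights, an exact permutation test over 924 splits, and leaving out each array. Averaging replicates 1 and 2, 3 and 4, and 5 and 6, or treating them as a random block, was added after the data were seen.

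The fit was tested on simulated data made from the means and spreads of the 3365 features, with 200 features changed in the ppi1 against WT comparison. It recovered 61% of changes of 0.5 and 91% of changes of 1 on the log2 scale, and 8.43% of its calls were false. That false share is higher than the threshold on adjusted p aims at. Means and spreads alone carry no correlation between arrays, such as that of same-numbered or neighbouring replicates. These shares therefore apply to arrays without such correlation and may not hold for the real arrays.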

Results

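The transcript levels of 12 Arabidopsis arrays were compared between wild type and ppi1, a mutant impaired in the import of precursor proteins into chloroplasts. ppi1 is known as a mutant of TOC33 (AT1G02280), which encodes a receptor of the protein import machinery in the outer chloroplast envelope. The comparison asks which nuclear transcripts differ in level when import is impaired. Each group had 6 arrays. Summed deposited intensities ranged from 3380 to 3582 over the WT arrays and from 3598 to 3689 over the ppi1 arrays.

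No feature in the annotation used was assigned to TOC33, so the targeted gene could not serve as a check of the labels. None of the 26 listed genes of the import machinery was measured by a feature of its own. The labels were therefore taken as given.

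The transcript signal of LHB1B2 (AT2G34420, also LHCB1.5), a chlorophyll a/b-binding protein of the photosystem II antenna, had the lowest adjusted p among the named genes and fell. It was 15.5 ± 1.03 (SD, n = 6) in WT and 7.50 ± 0.385 (SD, n = 6) in ppi1. This is a log2 fold change of -1.05 (SE 0.0505, adjusted p = 4.32e-07), with ppi1 lower in 6 of 6 replicate numbers. The LHCB1 genes are close copies of each other, so the feature can pick up several of them. PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, fell from 1.48 ± 0.335 to 0.842 ± 0.254, a log2 change of -0.82 (SE 0.200, adjusted p = 0.0271). The PRK call was lost in 8 of the 12 fits that left out 1 array (0.0520 to 0.0578), in the exact permutation test (adjusted p = 0.0719), and with adjacent replicates as a random block (0.209) or averaged (0.331). PSBY (AT1G67740), a small photosystem II subunit, fell from 2.52 ± 0.297 to 1.80 ± 0.271, a log2 change of -0.49 (SE 0.110, adjusted p = 0.0181). It was at -0.77 with median scaling, and its call was lost in the exact permutation test (adjusted p = 0.0719) and with adjacent replicates as a random block (0.0693) or averaged (0.345).

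The other photosynthesis features did not pass the test. PSAN, a photosystem I subunit, had a log2 change of -0.33 (SE 0.176, adjusted p = 0.309), passed with median scaling (-0.68, adjusted p = 0.0356) and was at -0.19 without WT replicate 1 (adjusted p = 0.452). SBPASE, the sedoheptulose bisphosphatase of the Calvin cycle, was at -0.13 (SE 0.170, adjusted p = 0.747). PSBW, another small photosystem II subunit, was 26.9 ± 2.63 in WT and 32.5 ± 3.10 in ppi1, a log2 change of 0.27 (SE 0.0801, adjusted p = 0.0609). The directions of PSBW and SBPASE depended on the scaling. PSBW was at -0.20 and SBPASE at -0.22 with median scaling, against 0.07 and 0.06 on the deposited scale.

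**Figure D1:**
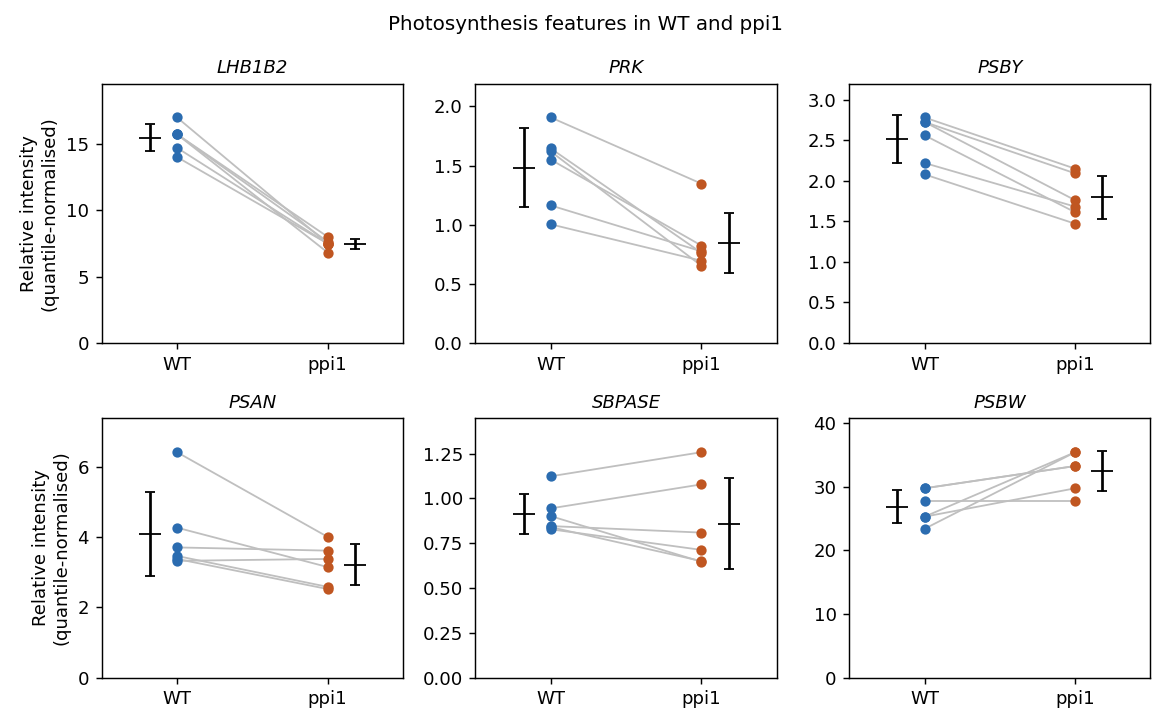
Quantile-normalised relative intensity (y axis, from 0) of the 6 photosynthesis features with 1 assigned gene in WT and ppi1. Points are arrays, grey lines join arrays of the same replicate number, and black bars give the mean ± SD of 6 arrays; LHB1B2, PRK and PSBY are lower in ppi1 in 6 of 6 replicate numbers, while PSBW was 26.9 in WT and 32.5 in ppi1, a direction that flips with median scaling (-0.20).

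Over the 6 measured photosynthesis genes, 3 fell, 0 rose and 3 did not pass, and 4 passed when adjusted over the list alone, PSBW being the one added, with a positive log2 change. Their median log2 change was -0.41, or -0.72 with median scaling, and camera placed the list below the other features (adjusted p = 0.00748). With an estimated correlation this call was lost (adjusted p = 0.110). In fry, which tests whether the genes of a list move one way on balance and not whether they differ from other genes, its adjusted p was 2.25e-05. The list was joined after the names and some values had been seen, so it is not independent evidence of its direction. The words photosystem and light-harvesting were fixed in advance, but were searched in gene symbols and synonyms, not in gene descriptions as planned. The 3 features they found were LHB1B2, PSBY and PSBW, without the photosystem I subunit PSAN. All 3 are also in the joined list, so the lists are not separate evidence. Of the 3, 2 fell, 0 rose and 1 did not pass. When adjusted over the list alone 3 passed, PSBW with a positive log2 change. The median of the word list, which is the value of PSBY, was -0.49, or -0.77 with median scaling. Its fry adjusted p was 2.23e-06. Its camera adjusted p was 0.0342, which became 0.147 with an estimated correlation. That call was also lost with the replicate block (adjusted p = 0.0770), without WT replicate 2 (0.0514), without WT replicate 5 (0.0626) and without WT replicate 6 (0.0506).

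Of the 5 measured genes of nuclear-encoded plastid ribosomal proteins, 0 passed over all features in limma and 0 when adjusted over the list alone, 3 had a positive and 2 a negative log2 change, and the median was 0.19 (camera adjusted p = 0.268, and 0.285 with an estimated correlation; fry adjusted p = 0.0610). The median was 0.107 without ppi1 replicate 6 and 0.12 with array weights. AT3G13120, which encodes plastid ribosomal protein S10, had the smallest adjusted p among them. It was 0.170 ± 0.0467 in WT and 0.288 ± 0.112 in ppi1, near the floor of 0.118, a log2 change of 0.70 (SE 0.291, adjusted p = 0.187). On the deposited scale its adjusted p was 0.0126. All 3 members with a positive change had arrays at the floor. These were 6 for AT1G64510, whose change is the median, 4 for AT1G29070 and 1 for AT3G13120. The 2 members with a negative change, AT4G01310 and AT3G54210, had 0, so the sign of the median rests on features near the floor.

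Other plastid pathways were each represented by 1 or 2 genes. AT3G58610, the ketol-acid reductoisomerase of branched-chain amino acid synthesis, fell from 0.470 ± 0.0368 to 0.375 ± 0.0354, a log2 change of -0.33 (SE 0.0715, adjusted p = 0.0173). On the deposited scale its change was -0.06 (adjusted p = 0.673). In chlorophyll synthesis, 0 of 2 genes passed. AT1G74470, the geranylgeranyl reductase, had a log2 change of -0.23 (SE 0.144, adjusted p = 0.400) and CHLM, the magnesium protoporphyrin methyltransferase, of 0.18 (SE 0.150, adjusted p = 0.568), although CHLM was higher in ppi1 in 6 of 6 replicate numbers and passed with the replicate block (adjusted p = 0.0252). CHLM was at 0.39 on the deposited scale (adjusted p = 0.0759). It did not pass with adjacent replicates averaged (adjusted p = 0.856), nor with these averages in a block (adjusted p = 0.233). AT1G74470 was at -0.45 with median scaling and at -0.14 without ppi1 replicate 6. FATB, a plastid acyl carrier protein thioesterase, was at 0.0086 on the log2 scale (SE 0.271, adjusted p = 1). AT3G52960, the plastid peroxiredoxin IIE, was at -0.19 (SE 0.194, adjusted p = 0.641), although ppi1 was higher in 4 of 6 replicate numbers. It was at -0.08 without WT replicate 5, -0.09 without WT replicate 6, -0.09 with array weights and -0.41 with median scaling. The copper chaperone CCS was at -0.32 (SE 0.164, adjusted p = 0.284), but 4 of its 6 ppi1 arrays were at the floor, so the size of this difference is not well defined. It was at -0.03 on the deposited scale (adjusted p = 0.895), -0.18 with cyclic loess, and -0.46 without ppi1 replicate 2, where it passed (adjusted p = 0.0252). NTRC, a plastid thioredoxin reductase, was at 0.10 (SE 0.0877, adjusted p = 0.589), with 0.28 on the deposited scale, 0.0056 with median scaling and 0.06 without WT replicate 3. Of the markers of senescent and of non-green tissue fixed in advance, 0 were measured by a feature with 1 gene. The same held for the listed loci of electron carriers and ATP synthase, photorespiration, isoprenoid synthesis, plastid transcription, plastid proteases and chaperonins, starch metabolism and reference genes. The word lists of cytosolic ribosomal proteins, tRNA synthetases, pentatricopeptide repeat proteins, kinases, transcription factors, cytochromes P450 and glutathione transferases, which searched gene symbols and synonyms alone, found 0 features. These lists do not hold every gene of their class, so a count of 0 does not mean that the class was unmeasured: ATSIK, a kinase, and Cpn60beta3, a plastid chaperonin subunit, had features but were in none of them.

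Among all named genes past the threshold, the largest decrease was that of AT4G08940, from 0.727 ± 0.0902 to 0.302 ± 0.0313, a log2 change of -1.27 (SE 0.0932, adjusted p = 1.90e-05). AT4G31530 fell from 17.3 ± 3.28 to 7.55 ± 2.42, a change of -1.25 (SE 0.239, adjusted p = 0.00855). Besides these, LHB1B2 and PRK, the 10 largest decreases held AT3G47980 (-0.82), AT4G19900 (-0.76), AT4G29750 (-0.75), AT1G68660 (-0.75), AT1G34270 (-0.67) and AT5G17630 (-0.62). AT1G68660 encodes ClpS1, an adaptor of the plastid Clp protease, and AT5G17630 the xylulose phosphate translocator of the plastid envelope. Adjusted p-values of these 6 genes ran from 0.00126 for AT3G47980 to 0.0255 for AT4G19900. Each of the 10 was lower in ppi1 in 6 of 6 replicate numbers. AT3G47980 was at the floor on 2 ppi1 arrays, and its change was -0.50 on the deposited scale and -0.53 with an offset in place of the floor. AT1G34270 was at -0.41 on the deposited scale. Which gene fell most depended on the scaling. AT4G31530 was at -1.37, LHB1B2 at -1.26 and AT4G08940 at -1.02 on the deposited scale. With median scaling they were at -1.65, -1.53 and -1.29.

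The increases were smaller. ATSIK (AT3G08760) rose from 0.840 ± 0.0475 to 1.34 ± 0.203, a log2 change of 0.66 (SE 0.0903, adjusted p = 0.00142), and AT4G39760 rose from 3.18 ± 0.487 to 4.67 ± 0.499, a change of 0.56 (SE 0.107, adjusted p = 0.00855). The others among the 10 largest increases were AT4G27250 (0.56), AT1G76050 (0.55), AT1G08845 (0.52), AT4G22370 (0.52), AT2G04790 (0.49), AT5G52960 (0.48), AT5G10910 (0.38) and Cpn60beta3 (0.37). Cpn60beta3 (AT5G56500) is a subunit of the plastid chaperonin, AT5G10910 belongs to the MraW family of ribosomal RNA methyltransferases, and AT1G76050 to the pseudouridine synthases. Adjusted p-values of these 8 genes ran from 0.00239 for AT4G22370 to 0.0313 for AT1G76050, and each of the 10 was higher in ppi1 in 6 of 6 replicate numbers. On the deposited scale AT5G52960 was at 0.77 and Cpn60beta3 at 0.64. With median scaling AT4G39760 (0.18, adjusted p = 0.198), AT4G27250 (0.38, adjusted p = 0.0520) and AT5G10910 (0.25, adjusted p = 0.0565) no longer passed. The calls of 5 genes were lost when certain single arrays were left out. For PRK the arrays were WT replicates 1, 2, 5 and 6 and ppi1 replicates 3, 4, 5 and 6. For AT1G76050 they were WT replicates 1 to 5 and ppi1 replicates 3 and 6 (adjusted p = 0.0510 to 0.0721), and for AT2G04790 WT replicates 2 to 6 and ppi1 replicates 1 and 4 (0.0531 to 0.0709). For Cpn60beta3 they were WT replicates 3 and 4 and ppi1 replicates 1 and 4 (0.0505 to 0.0571), and for AT4G19900 WT replicates 2, 3 and 4 (0.0539 to 0.0570). Each such fit kept the neighbour of the array left out, so it tests little if adjacent replicates are not independent. With adjacent replicates averaged, LHB1B2 alone kept its call among the 10 largest increases and 10 largest decreases (adjusted p = 0.0211). As a random block, AT1G76050 (0.167), AT1G08845 (0.145), AT2G04790 (0.178), AT5G52960 (0.0769), AT5G10910 (0.0553), Cpn60beta3 (0.207), AT4G19900 (0.0633) and PRK (0.209) lost theirs.

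**Figure D2:**
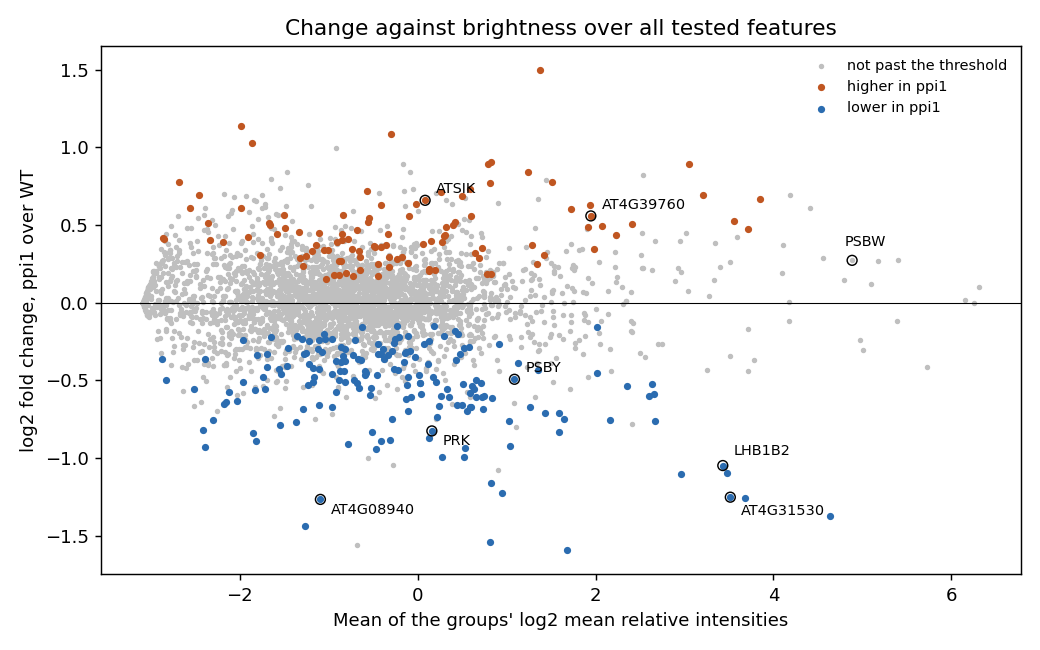
Log2 fold change of ppi1 over WT (y axis) against the mean of both groups' log2 mean relative intensities (x axis) for the 3365 tested features. Coloured points passed the adjusted p of 0.05, with 106 higher and 178 lower in ppi1; named points are circled, and of these LHB1B2 is at -1.05, AT4G31530 at -1.25 and PSBW, which did not pass, at 0.27 (-0.20 with median scaling).

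In all, 284 of 3365 features (8.44%) passed, with 106 higher and 178 lower in ppi1. The median size of their log2 change was 0.475, and 4 rose and 12 fell by 2-fold or more. Of the 284, 50 had 1 gene (20 higher, 30 lower), 75 had several and 159 had none. ppi1 lay on the same side of WT in 6 of 6 replicate numbers for 274 of them. The features were called on these same arrays, so such counts, here and for single called genes above, are not separate support. The 6 numbers may also not be independent. With the replicate block, 517 features passed (250 higher, 267 lower), of which 254 were shared with the 284 in the same direction.

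The split of directions depended on the scaling. On the deposited scale the median log2 change over all features was 0.206, and 805 features were called higher and 104 lower. With median scaling 80 were higher and 336 lower. The calls are therefore changes relative to the other features of the array.

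Replicates 1 and 2, 3 and 4, and 5 and 6 of each group lay close together. Their median absolute log2 difference was 0.0861 to 0.122, against 0.158 to 0.314 for other pairs of arrays of a group. When each of these sets was averaged, which left 3 values per group, 4 features passed in limma, 0 higher and 4 lower, and all 4 were among the 284. At an unadjusted p under 0.05, 171 were then higher and 227 lower. LHB1B2 was the 1 named gene that still passed (adjusted p = 0.0211), while AT4G08940 (0.0747) and ATSIK (0.203) did not. With the averaged sets also taken as a block, 0 features passed in limma, the lowest adjusted p was 0.206, and 601 features had an unadjusted p under 0.05. As a random block, with a consensus correlation of 0.646, the sets gave 99 features, 28 higher and 71 lower.

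**Figure D3:**
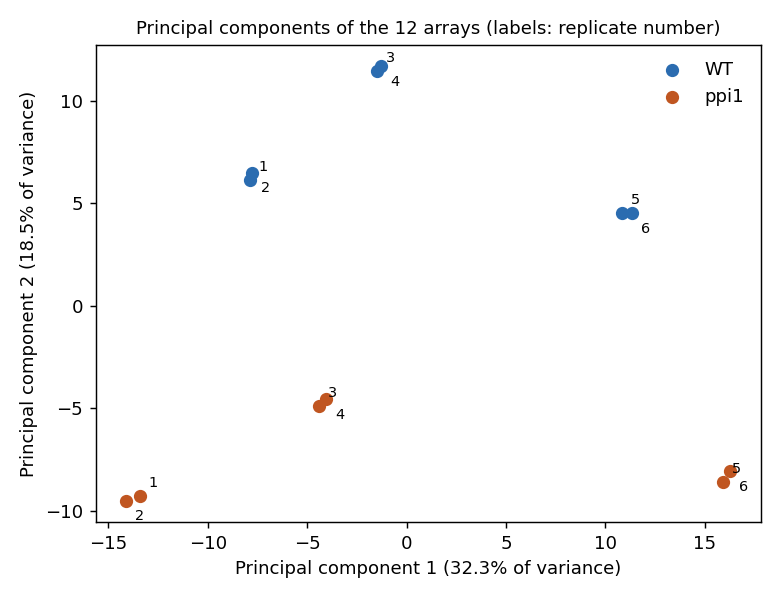
First (x axis) and second (y axis) principal components of the 12 arrays on normalised log2 intensities, explaining 32.3% and 18.5% of the variance. Points are arrays labelled with their replicate number; WT and ppi1 separate on the second component, and replicates 1 and 2, 3 and 4, and 5 and 6 of each group lie side by side.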

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

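In 5 of the 64 groups of 6 values examined, 1 array lay far from the other 5 by Dixon's test, and chance alone flags about 1 group in 20. PRK was at 1.35 in ppi1 replicate 1, against 0.653 to 0.823 in the other ppi1 arrays. PSAN was at 6.42 in WT replicate 1, against 3.33 to 4.27 in the other WT arrays. AT1G08845 was at 0.885 in WT replicate 6, against 1.11 to 1.21 in the others. CCS was at 0.118, just above the floor, in WT replicate 1, against 0.158 to 0.182 in the other WT arrays. It was at 0.212 in ppi1 replicate 2, against 0.118 to 0.121 in the other ppi1 arrays, of which 4 were set to the floor, so the floor itself narrowed their range and this value carries little weight.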

How the results depend on the processing

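The averaged and random-block settings and the joined photosynthesis list were chosen after the data were seen. Against 284 features (106 higher, 178 lower), the deposited scale gave 909 (805 and 104), and median scaling gave 336 lower features. The deposited scale leaves the higher ppi1 level in place, which was larger in dim than in bright features. It was 0.35 against 0.137 in replicate 3, but only 0.079 against 0.0257 in replicate 2. Median scaling removes 1 shift per array (0.35 in replicate 3 and 0.113 in replicate 2), so it lowers bright features more than their own shift. The photosynthesis features lay at the 72.2 to 99.7 percentile of brightness. The replicate block gave 517 (250 higher), averaging adjacent replicates 4 (0 higher, 4 lower), averaging with the replicate block 0 (0 and 0), and the random block 99 (28 and 71); the averaged settings have fewer values per group, and at an unadjusted p under 0.05 limma gave 398 and 601. The exact permutation test gave 205, with PRK (adjusted p = 0.0719), PSBY (0.0719) and AT1G76050 (0.0562) no longer called, and leaving out each array gave 222 to 277. Of the 2 lists fixed in advance and tested, 1 passed, the word list, whose words were searched otherwise than planned. The number of lists passing became 0 with array weights, the replicate block, camera with an estimated correlation and both averaged settings. It ranged from 0 to 1 when each array was left out, and the cause was not tested. The median of the word list was -0.49, with -0.77 under median scaling and -0.48 under array weights (adjusted p = 0.0622). Averaging (0.0630) and averaging with the block (0.127) ended the call, and leave the median at -0.49 by construction. Without each array it ran from -0.55 to -0.44. The joined photosynthesis list (-0.41, or -0.72 under median scaling) lost its call with an estimated correlation. The ribosomal list ran from 0.107 to 0.232 without each array. FATB, near the floor and never called, changed sign when single arrays were left out (-0.11 to 0.15). No other gene named by the rule changed sign under any setting run. Of the 29 genes named by the rule, 22 had a call in the main fit. Of these 22 calls, 3 were lost with median scaling, 1 on the deposited scale and 21 with averaging. All 22 were lost with averaging and the block, and 10 with the random block. The replicate block changed no call among the 29. Settings for TOC33 were not run because no feature was assigned to it, and without the dimmest features the ribosomal list was too small to test.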

Other observations

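The tests of independence between replicates and of the brightness of the photosynthesis features were chosen only after the results were seen. The spreads set beside the tests of a few abundant features and of bright spots, the values relative to all features and the spread of the matched lists were also added then, and the group medians and counts of zeros were known before the scale was tested.

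Several called genes outside the naming rule, chosen after their values were seen, belong to other pathways. GLDH (AT3G47930), the last enzyme of vitamin C synthesis, fell from 0.526 ± 0.0407 to 0.378 ± 0.0362 (SD, n = 6), a log2 change of -0.48 (SE 0.0719, limma adjusted p = 0.00243), and was lower in ppi1 in 6 of 6 replicate numbers. On the deposited scale its change was -0.21 (limma adjusted p = 0.0969). AT3G23940, the dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose from 1.39 ± 0.0292 to 1.75 ± 0.175, a change of 0.32 (SE 0.0590, limma adjusted p = 0.00773). AT3G58610, which acts just before it in that pathway, fell by 0.33, but was at -0.06 on the deposited scale (limma adjusted p = 0.673). With adjacent replicates averaged, none of GLDH (limma adjusted p = 0.202), AT3G23940 (0.278) and AT3G58610 (0.232) passed.

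Features with no gene in the annotation had changes as large as any named one. Feature 886 had the next to largest decrease among called features without a gene, from 2.99 ± 0.515 to 1.03 ± 0.175 (SD, n = 6), a log2 change of -1.54 (limma adjusted p = 6.84e-05). Feature 2711 had the next to largest increase among them, from 0.176 ± 0.0916 to 0.364 ± 0.0861, a change of 1.14 (limma adjusted p = 0.0356). Its WT mean was near the floor of 0.118, so the size of this change may depend on the floor. With adjacent replicates averaged, neither feature passed (limma adjusted p = 0.116 and 0.203).

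The first pattern is the number of features past the threshold. Of 100 splits of the 12 arrays into 6 and 6, 1 gave as many features as 284, the real one, and the highest other gave 27; of the 32 splits that part all replicate numbers, again 1 did, and the highest other gave 6. The former put replicates 1, 2 and 4 of both groups on one side, which parts replicates 3 and 4, and the latter exchanged replicates 1 and 2 between the groups. The mean correlation of deviations within the adjacent sets was 0.328, from -0.0248 to 0.672 over the single sets, and of all ways of setting the replicates in pairs, 1 was as high, these sets themselves, with 0.246 for the next, so a candidate explanation is that some sets share a plant sample or a hybridisation day. If each set counts as 1 sample, 4 splits part the sets, too few for a share under 0.05, and the 284 calls may then overstate the evidence for single genes.

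The next pattern is the higher deposited intensity of ppi1 over all features, a difference of 0.274 between the groups' median log2 values. Scaling each array to its total without the brightest 1% of features left 0.167, with 0.0816 to 0.215 over the replicate numbers. A value staying above 0.10 was set in advance to count against a few abundant features as the cause. The difference stayed above it, but replicate 2 lay below, so such features may account for part of it. The brightest 1% took a larger share in ppi1 than in WT in replicates 1 (27.52% against 26.34%) and 2 (27.57% against 26.31%), and a smaller one in replicates 3 to 6. Dim features exceeded bright ones in their ppi1 shift by a median of 0.183, over 0.10 in 4 of 6 replicate numbers and down to 0.0533 in the others. Those 4 were replicates 3 to 6, which are adjacent sets and may not count separately. Because the excess was not large in all 6, the test does not decide whether additive background was left in the ppi1 arrays. A difference in RNA composition between the genotypes was not tested and cannot be told apart from it here. The genotype itself stays an untested explanation.

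The last pattern is the lower signal of LHB1B2 and the negative median of the 6 photosynthesis features, of which 3 fell and PSBW had a positive change. On the deposited scale LHB1B2 was at -1.26, while the 41 features within 2-fold of its brightness had a median of -0.107 (bootstrap interval -0.488 to 0.0709), and 4 of the 41 were as low. Relative to the median of all features on that scale, 0.206, these values become -1.46 for LHB1B2 and -0.313 for its neighbours (-0.694 to -0.135). Compression of bright spots in ppi1 would have to lower the neighbours about as much, which argues against it as the whole cause, but bright features were lower as a set and a contribution stays open. Random lists matched on mean intensity had medians centred on 0.01 (5th to 95th percentile -0.22 to 0.21), against -0.41 for the 6 photosynthesis features, at the 0.45 percentile of 10000 such lists. These medians are on the quantile-normalised scale, which largely removes shifts shared by features of like brightness. The matched lists would therefore centre near no change in any case. On this scale brightness alone would put the list near the matched ones. It is thus unlikely to be the whole cause of the difference that the scaling left, and nothing is shown for the deposited scale. The percentile is not a test of the list, which was joined after some values were seen and whose genes are correlated. Plant age, tissue make-up and signal from related LHCB1 genes were not tested, and the genotype stays a hypothesis.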
